A study of Mus musculus with 7 samples.

How the data were processed

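Single-cell RNA sequencing (10x Chromium, 3' end tags, v3.1 chemistry) was performed on 7 mouse libraries. The mice carried a RIT1-M90I allele with floxed p53 (Trp53) and Nf2, activated in the lung with SPC-Cre, a recombinase driven by the surfactant protein C promoter. Tumor 1 was sequenced as 2 libraries and tumor 2 as 1 library. A pair of libraries came from adjacent normal lung of 1 animal, and another pair from replicate cultures of RPNS, a cell line grown from a tumor of the same genotype. Tissue was dissociated enzymatically, red cells were lysed and nothing was sorted, per the labels. The labels pair the lung with a tumor named in a way that matches no library, so which of the tumors came from the same animal is unknown here.

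The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, neither scaled nor pooled. They were made with Cell Ranger 7.1.0 against mm10, per the submitters' processing notes, and barcodes had already been filtered. The reference held 32286 features, among them a feature named RIT1 beside the mouse gene Rit1. RIT1 was taken here as the mutant transgene, which the notes do not state. The 7 matrices held 44887 barcodes, with total counts from 19945598 UMIs in tumor 2 to 96755818 UMIs in line replicate 1.

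Cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. Doublets were scored per library with the Scrublet method in scanpy 1.11.5 (expected doublet rate 6%). Its automatic thresholds called from 0 to 3.36% of cells. A fixed score of 0.2 was used instead, which removed 4.12% and 3.04% of cells in the lungs, 2.07% and 1.73% in the libraries of tumor 1 and 1.17% in tumor 2. In the line, taken as 1 cell type, none were removed, where the automatic thresholds called 0.291% of cells in replicate 1 and 0 in replicate 2. This left 39601 cells, with median depths from 3585 UMIs per cell in lung 1 to 39448 UMIs in line replicate 1. The minimum of 500 genes excluded 39.6% of the barcodes of tumor 2 and at most 12.4% of those of any other library, so shares in tumor 2 rest on the barcodes that remained. The mitochondrial limit excluded 24.8% of the barcodes of tumor 2 and at most 5.66% of those of any other library.

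Cells were clustered on 2000 variable genes, ranked per library, 30 principal components and 15 neighbors, weighted by shared neighbors, with the Leiden method (igraph 0.11.9, resolution 1, seed 1) and no correction between libraries, giving 46 clusters. All cells of the line were kept as 1 group, though they spread over 5 clusters, of which 1 held 1995 cells of replicate 1 and 201 of replicate 2 and another 12 and 3182. A cluster took the name of the class whose markers scored highest (at least 0.5) when at least 3 markers were detected in 10% of its cells and when its 10 leading genes, ranked among genes detected in 25% of cells, held no more markers of another class than of its own. Names are marker-based and each stands for a class-like group. Clusters with RIT1 above 50 CPM (UMIs of a gene scaled to a fixed library total) were named as carrying the transgene; this limit was chosen after the data were seen. CPM of samples in an edgeR comparison, of the plot of gene levels and of lists compared between classes use TMM-scaled totals. CPM given by library, those of RIT1, Rit1, Trp53 and Nf2 by cell group, those of cells outside a comparison and pooled ratios use plain totals. Carcinoma-like cells carry epithelial keratins and RIT1, and a RIT1-positive cluster with fibroblast collagens was kept apart as mesenchymal. Clusters that met no rule stay unnamed. Shares of classes are given with exact (Clopper-Pearson) 95% intervals and were not tested, since the lungs are 1 animal. Intervals cover counting error only. A count of 0 was given a limit of 3 counts over the group.

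Counts were summed per class and sample, with the libraries of tumor 1 added together and at least 20 cells needed per sample. The main test was edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). Tumor, lung and line were fitted together, with 2 samples each and 3 residual degrees of freedom; classes other than carcinoma, AT2 (alveolar type 2) and line were fitted with 4 samples and 2 residual degrees of freedom. Fitted p-values measure the spread between 2 tumors, 2 samples of 1 lung and 2 cultures of 1 line, not between animals or lines, and are too small to that extent. Batch 231205 holds only tumor 1 and batch 240410 only line replicate 1, so a batch term leaves each contrast to batch 240705 (tumor 2, both lung samples, line replicate 2), and that batch was also analysed alone. Alone, that batch leaves the spread to the 2 samples of 1 lung, so counts from it do not measure the spread between tumors. The common biological coefficient of variation was 0.290 in the cell comparisons and 0.311 in whole tissue.

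Genes are named by 1 rule: up to 12 with the largest rise and 12 with the largest fall (6 and 6 in the other classes) among genes past the test, with at least 50 CPM in the higher group and no overlap between samples, leaving out unnamed transcripts, mitochondrial, ribosomal, hemoglobin and immunoglobulin genes and the markers that named the cells; up to 4 members with the smallest p of each gene list; then Rit1, Trp53, Nf2, Yap1, Wwtr1, Tead1 and Tead4. RIT1 was added to them after the features were seen. Genes named in the account of tumor 1 against tumor 2, and markers and leading genes of clusters, fall outside the rule and were picked after their values were seen. Folds against a group with 0 counts are lower bounds against the limit of 3 counts over the group; with 1 to 3 counts the ratio of pooled CPM is given with its exact interval. Positions are from GENCODE vM21 (GRCm38, the assembly called mm10), which placed 289 of the 290 named features; RIT1 has none.

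The 21 gene lists were YAP/TEAD targets, MAPK output, mesenchymal genes, epithelial junctions, alveolar lineage, injury-related transitional state, gut lineage, basement membrane and integrins, p53 targets, proliferation, hypoxia and glycolysis, interferon response, MHC class I, MHC class II, dissociation stress, tumor macrophage, activated fibroblast, tumor endothelium, T cell activation and exhaustion, naive T cell and tumor neutrophil. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, at least 5 tested members), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists, comparisons, tests, naming rule, cell filters and alternative settings, apart from those named as added, were fixed before the data were examined.

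The tests of genes and lists were run on simulated counts per sample, while cell filters, doublet calls, clustering and naming were not simulated: negative binomial counts were drawn with the depths, spread and design of the data, and 200 genes were changed 2-, 4- or 8-fold. Of the genes changed 4-fold, edgeR recovered 60.6% in carcinoma-like against AT2-like cells, 65.7% in the line against carcinoma-like cells, 47.7% in the line against AT2-like cells, 64.2% in whole tissue, 67.7% in neutrophils and 95.5% in macrophages. Of those changed 2-fold, it recovered from 1.61% in neutrophils to 29.2% in macrophages. False calls were from 3 of 81 to 6 of 113. Among 100 null lists, camera at its preset correlation called at most 4 at an unadjusted p under 0.05. With an estimated correlation it called 0 of 100 in each simulated comparison. Recovery of a changed list was not measured with that setting, so the lack of a call there does not show that a list was unchanged. Simulated genes varied independently, so these counts do not show whether the preset correlation suits genes that vary together.

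Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the 3 tumor libraries apart, the 2 lung samples summed, batch 240705 alone, the sample number as a replicate block, each sample left out, a fold of at least 2, doublets kept, at least 1000 genes and at most 10% mitochondrial UMIs, Leiden resolution 2, and each sample thinned to 43 cells and 371210 UMIs. Added after seeing the data were carcinoma-like cells above 10000 UMIs and the mesenchymal cluster joined to carcinoma-like cells. The stricter filter and the kept doublets were first clustered anew; the stricter filter then named no AT2 class and the kept doublets merged club with AT2 cells. After that was seen, these alternatives were switched to class names carried over from the first clustering, and the clusterings anew are given as added ones. RIT1 was also compared between classes after thinning each cell to 2000 UMIs.

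Cell cycle phase calls and trajectories were not used here. Classes with under 20 cells in any of the 4 tissue samples (alveolar macrophage, monocyte, endothelial, fibroblast, mural, mesothelial, natural killer, plasma, ciliated, club, mast cell) were not tested between tumor and lung. Analyses used Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9) and R 4.3.3.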

Results

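Gene expression was measured in single cells of 2 lung tumors, of adjacent normal lung and of RPNS, a cell line grown from a tumor, all from mice with the M90I mutant of RIT1 and floxed p53 and Nf2, treated with SPC-Cre. RIT1 is a RAS-family small GTPase, p53 a tumor suppressor and Nf2 (merlin) an upstream activator of the Hippo pathway, which restrains the transcriptional co-activator YAP. The groups held 2 tumors (3 libraries), 2 samples of 1 lung and 2 cultures of 1 line. Total counts were 66157412 and 60248017 UMIs in the libraries of tumor 1, 19945598 UMIs in tumor 2, 54659361 and 51853465 UMIs in the lung samples and 96755818 and 62967919 UMIs in the cultures. After filtering, the libraries of tumor 1 gave 5437 and 5291 cells, tumor 2 gave 1600 cells, the lung samples 8636 and 6342 cells and the cultures 2408 and 9887 cells. All values below carry n = 2 per group unless a single sample is named.

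The first question was which cells the tumors and the adjacent lung held. Carcinoma-like cells, defined by keratins and the RIT1 feature, made up 15.7% of tumor 1 (95% interval 15.02 to 16.4%) and 9.56% of tumor 2 (8.17 to 11.1%), against 0.371% and 0.363% of the lung samples. Neutrophil-like cells were 11.6% and 43.3% of the tumors against 6.98% and 8.55% of the lungs, and macrophage-like cells 16.3% and 10.4% against 4.78% and 5.08%. Endothelial-like cells, which line blood vessels, made up 27.6% and 27.3% of the lungs but 0.0932% of tumor 1 (10 cells) and 0 of 1600 cells in tumor 2. An unnamed cluster with the endothelial genes Selp, Emcn and Col4a1 among its leading genes held 304 further cells of tumor 1. It held 7 cells of tumor 2 and 89 and 69 of the lungs. Endothelial markers scored highest in unnamed clusters led by Epas1 and by Gucy1a1. These held 160 and 131 cells of lung 1, 186 and 87 of lung 2, 14 and 0 of tumor 1 and 3 and 0 of tumor 2. Monocyte-like cells were 0.298% and 1.13% of the tumors against 13.5% and 13.5% of the lungs, T-like cells 2.51% and 7.13% against 13.7% and 12.6%, and B-like cells 1.44% and 5.63% against 9.26% and 8.58%. Alveolar macrophage-like cells differed between the tumors, with 14.7% in tumor 1 and 0.563% in tumor 2, against 5.58% and 5.72% in the lungs. Unnamed cells were 20.9% and 15.6% of the tumors, and 1628 of those in tumor 1 formed a cluster led by Arg1, Ccl24 and F13a1.

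As tumor minus lung, mean shares differed by -27.4 points for endothelial-like cells (spread between replicates 0.155 points, SD), -12.8 points for monocyte-like cells (0.415), -8.34 points for T-like cells (2.38), 8.41 points for macrophage-like cells (2.97), 12.3 points for carcinoma-like cells (3.07), 19.7 points for neutrophil-like cells (15.9) and 1.96 points for alveolar macrophage-like cells (7.05). This spread pools the SD between the tumors with that between samples of 1 lung, so it is not one between animals. Endothelial-like values leave out the unnamed clusters with endothelial genes given above, so their difference and small spread cover named cells only. The difference was below the spread for alveolar macrophages and little above it for neutrophils. For neutrophils the difference was below the SD of 22.4 points between the tumors, against 1.11 points between the lung samples. With at least 1000 genes and at most 10% mitochondrial UMIs it was 11.3 points for neutrophil-like cells, and at Leiden resolution 2 it was 13.3 points for macrophage-like cells. Shares of 1 sample sum to a fixed total, and no test was run, since the lungs are 1 animal. Tumor 1 stands alone in its batch. Within batch 240705 the values of tumor 2 and the lungs are those given here.

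**Figure D1:**
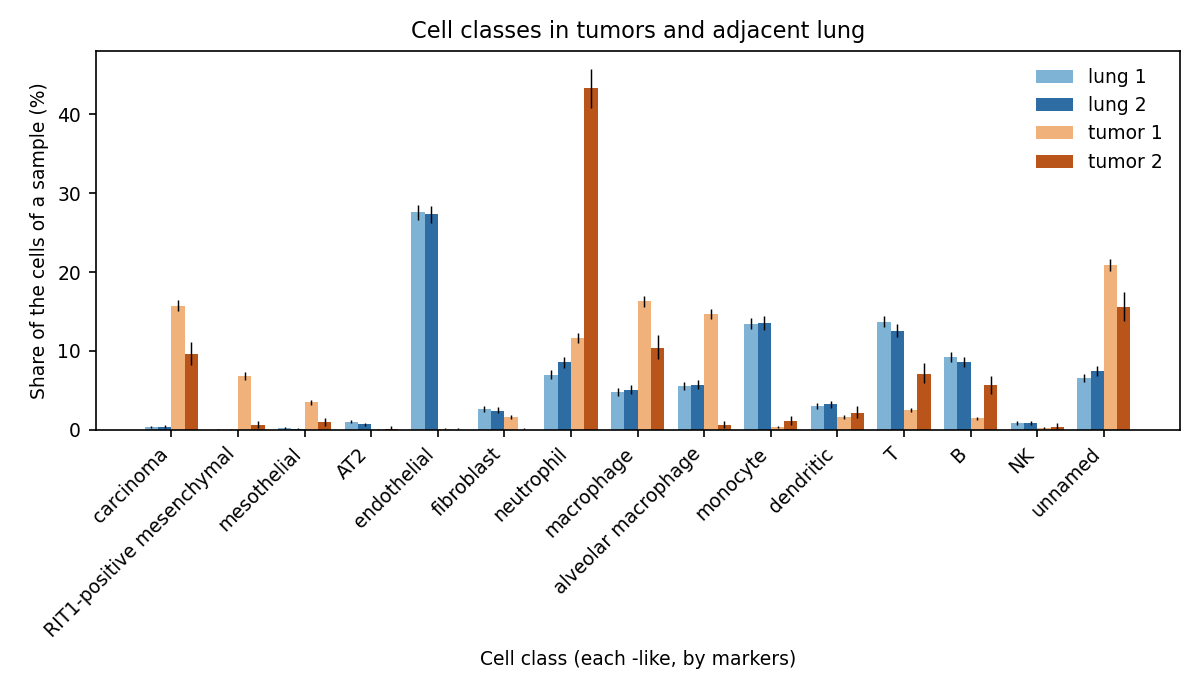
Share of the cells of each tissue sample (y axis, percent) in 15 cell classes (x axis); bars are samples and lines are exact 95% intervals. Endothelial-like and monocyte-like cells made up 27.6% and 13.5% of lung 1 and under 2% of either tumor, and neutrophil-like cells ranged from 6.98% in lung 1 to 43.3% in tumor 2. Unnamed cells include some with endothelial genes, which the endothelial-like bars leave out.

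RIT1, the feature taken as the transgene, was measured by cell group first, with the floxed genes. Carcinoma-like cells had 189 and 191 CPM of RIT1 in the libraries of tumor 1 and 95.03 CPM in tumor 2 (95% interval 85.2 to 106), and the line had 273 and 521 CPM, against 3.59 and 3.61 CPM in AT2-like cells of the lungs (4 and 3 UMIs). A RIT1 UMI was found in 72.1% of carcinoma-like cells of tumor 1 (median depth 20596 UMIs), in 30.1% of those of tumor 2 (3272 UMIs) and in 93.4% and 76.9% of the line's cells, against 0.604% and 0.894% of lung lymphocytes (2536 and 3839.5 UMIs), which serve as the level of free RNA. After thinning each cell to 2000 UMIs the shares were 25.8% and 7.83% in the tumors, 39.2% and 62.8% in the line and 0.454% and 0.557% in lung lymphocytes. In AT2-like cells 4 of 88 (4.55%) and 3 of 43 (6.98%) held a RIT1 UMI at median depths of 10432 and 16883 UMIs. No thinned AT2-like cell held one, which allows a UMI at that depth in up to 3.41% and 6.98% of cells (the limit of 3 counts). The mouse gene Rit1 (chromosome 3, 88716838 to 88731049, mm10) stood at 25.7 and 26.6 CPM in carcinoma-like cells of tumor 1, 19.8 CPM in tumor 2 and 20.6 and 20.5 CPM in AT2-like cells.

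Transcripts of the floxed tumor suppressor genes were counted in the tumors and the line. Trp53 (chromosome 11, 69580359 to 69591873) stood at 36.3, 33.9 and 15.4 CPM in the 3 tumor libraries, 10.8 and 22.9 CPM in AT2-like cells and 24.2 and 31.9 CPM in the line. Nf2 (chromosome 11, 4765845 to 4849536) stood at 49.9, 54.0 and 24.6 CPM, 35.9 and 31.3 CPM, and 43.3 and 52.99 CPM in the same order. The tags lie at the 3' end, and the labels do not state which exons the floxed alleles lose, so these counts do not show whether the genes were deleted.

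RIT1 was also counted in cells of adjacent lung. Carcinoma-like cells of the lungs (32 and 23 cells) had 126 and 101 CPM (95% intervals 108.5 to 145 and 85.4 to 119). Alveolar macrophage-like cells of the lungs had 17.1 and 16.0 CPM, or 0.137 and 0.171 UMIs per cell, against 0.809 and 1.36 CPM in those of the libraries of tumor 1. These macrophages form separate clusters in tumor 1 and in the lungs. Mesothelial-like cells of tumor 1 had 18.6 CPM, with a RIT1 UMI in 7.80% of cells (median depth 21330 UMIs) against 0.709% of lymphocytes of tumor 1 (2222 UMIs). Those lymphocytes had 2.60 CPM, with a RIT1 UMI in 3 of 423 cells. After thinning the shares were 1.36% (95% interval 0.443 to 3.14%) and 0.385% (0.00974 to 2.12%). These intervals overlap, but they rest on 5 of 368 and 1 of 260 cells and do not settle whether the classes differ.

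**Figure D2:**
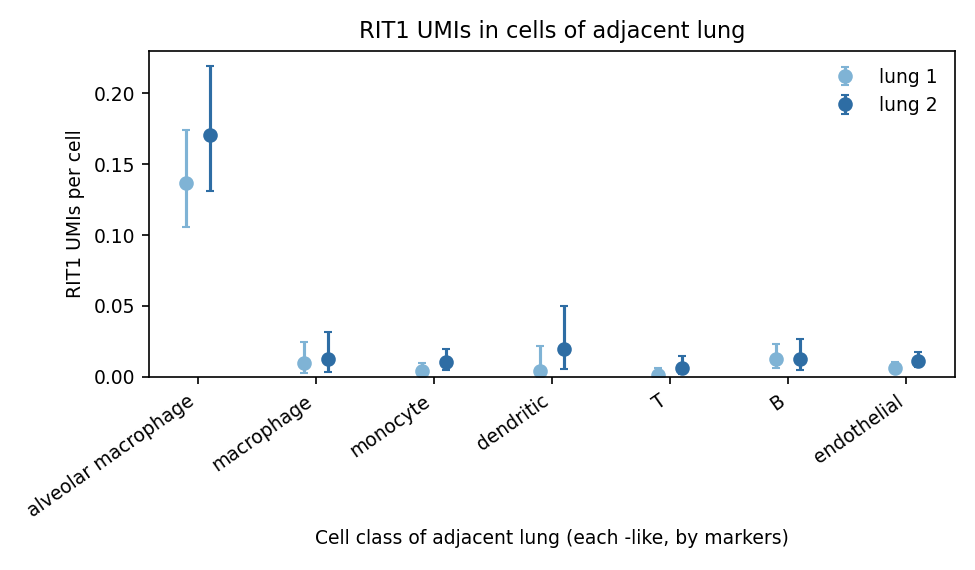
RIT1 UMIs per cell (y axis) in 7 cell classes (x axis) of the lung samples, with exact 95% Poisson intervals. Alveolar macrophage-like cells held 0.137 UMIs per cell in lung 1 (482 cells) and 0.171 in lung 2 (363 cells), and no other class shown exceeded an upper bound of 0.050.

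The comparison of carcinoma-like cells with AT2-like cells, the surfactant-making cells that SPC-Cre targets, addressed whether RIT1-mutant tumor cells carry YAP-related and EMT-like (epithelial to mesenchymal) programs. Camera called the lists of both gene groups higher at its preset correlation (adjusted p = 0.000219 and 0.0188) and neither with an estimated correlation (adjusted p = 0.156 and 0.375). In simulated counts the estimated correlation gave 0 calls among 100 null lists, which measures false calls only. Recovery of a changed list was not measured with it. The lack of a call with it, here and below, therefore does not show that a list was unchanged. The list calls depend on the preset correlation. The YAP target Ankrd1 (chromosome 19, 36111961 to 36120099) stood at 866 ± 548 CPM (SD) in the tumors and at 1 UMI in AT2-like cells, a ratio of 1163 (95% interval 209 to 45919). The mesenchymal cadherin Cdh2 (chromosome 18, 16588877 to 16809246) stood at 347 ± 120 CPM, 309 times its AT2 level (106 to 1499.8, 3 UMIs), while the junction gene Cldn3 fell by 9.25 on the log2 scale (SE 0.524, adjusted p = 2.11e-05) and the surfactant gene Sftpd by 10.01 (SE 0.427, adjusted p = 1.59e-05). Of 16551 genes tested with edgeR, 5202 changed, 2821 higher and 2381 lower in the tumors. With DESeq2 the larger part was lower (2686 higher and 2940 lower), as with RLE size factors (2495 and 2669) and when thinned (990 and 1281). RIT1 rose by 5.31 (SE 0.547, adjusted p = 0.000314), which is not independent of the carcinoma-like name, since RIT1 above a limit is part of it.

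Among the genes that rose most, all with 0 counts in AT2-like cells, were Hs6st2, a heparan sulfate sulfotransferase (at least 223-fold), Apob, the apolipoprotein of liver and gut (at least 276-fold), Gldc of the glycine cleavage system (at least 158-fold), the transcription factor Onecut2 and the sphingomyelinase Smpd3 (each at least 143-fold), the cadherin Cdh6 (at least 137-fold), the linker histone Hist1h1b (at least 118-fold), the annexin Anxa8 (at least 90.6-fold), the basal keratin Krt14 (at least 89.1-fold), the kinase Pak3 (at least 76.6-fold), the ubiquitin ligase Rnf128 (at least 73.3-fold) and the LIM protein Fhl2 (at least 66.5-fold). AT2-like cells held 1114043 and 830648 UMIs in 88 and 43 cells, which sets these bounds. Among the largest falls, 6 genes had 0 counts in the tumors: the chitinase Chia1 (at least 3853-fold), the protease inhibitor Spink5 (at least 1629.95-fold), Scgb1c1, Mlc1, Ly6i and Cst8 (at least 1037-, 1013-, 1004- and 873-fold). The complement gene Hc and the carbonic anhydrase-like Car8 fell by 12.07 and 12.11, and Enpep, Ces1d, Slco4c1 and Slc6a14 were left with 1 or 2 UMIs in the tumors, at ratios of 0.000105 (95% interval 2.65e-06 to 0.000588), 0.000128 (1.55e-05 to 0.000465), 0.000228 (2.75e-05 to 0.00083) and 0.00021 (5.28e-06 to 0.00118).

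YAP/TEAD targets rose in 13 of 22 members and fell in 1 (14 and 1 adjusted over the list alone, median 2.20). Beside Ankrd1, Tgfb2 (chromosome 1, 186622792 to 186705989) rose by 6.23 and Ajuba by 3.62, and Rbms3 fell by 3.19. The camera adjusted p = 0.000219, and the adjusted p = 0.156 with an estimated correlation. Yap1 itself (chromosome 9, 7931999 to 8004596) fell by 1.25 (SE 0.320, adjusted p = 0.0186), while its paralog Wwtr1 (-0.40) and the partners Tead1 (0.50) and Tead4 (0.35) did not pass the test (adjusted p = 0.272, 0.139 and 0.593). Mesenchymal genes rose in 10 of 27 members and fell in 3 (12 and 5 adjusted over the list alone, median 1.04, adjusted p = 0.0188, and adjusted p = 0.375 with an estimated correlation). Vim (chromosome 2, 13573927 to 13582826), an intermediate filament protein, rose by 3.04 and the collagen crosslinker Loxl2 by 3.74, and the matrix protein Thbs1 fell by 3.00. Epithelial junction genes fell in 15 of 21 members (16 adjusted over the list alone, median -2.69, adjusted p = 4.16e-08, and adjusted p = 0.156 with an estimated correlation), among them the splicing factor Esrp1 (-8.23), Rab25 (-8.24) and the transcription factor Grhl2 (-6.98). MAPK output genes went both ways, 4 up and 6 down of 14 (5 and 6 adjusted over the list alone, adjusted p = 0.409). Etv5 fell by 6.66, Phlda1 by 2.09 and Spry2 by 2.02, and Etv4 was at least 8.73-fold higher. Their median of 0.06 and mean of 0.15 were positive where camera's direction was down.

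Alveolar lineage genes fell in 13 of 15 members (13 adjusted over the list alone, median -3.98, adjusted p = 3.45e-11, and adjusted p = 0.156 with an estimated correlation), among them Chil1 (-11.73) and the surfactant lipid enzyme Lpcat1 (-5.37). This list is not independent of the AT2 name. Injury-related transitional genes rose in 6 of 11 and fell in 2 (7 and 3 adjusted over the list alone, median 2.70, or 1.74 with genes at 0 counts at their bound, adjusted p = 0.0184, and adjusted p = 0.213 with an estimated correlation). Sprr1a rose by 6.89, Clu by 4.09, Lgals3 by 3.68 and Tnfrsf12a by 2.70. Gut lineage genes rose in 3 of 7 (3 adjusted over the list alone, median 7.82, or 3.40 with bounds, adjusted p = 0.0209, and adjusted p = 0.213 with an estimated correlation): Lgals4 rose by 3.40, and the transcription factors Hnf4a and Pdx1 were at least 52.2-fold and 12.96-fold higher. Proliferation genes rose in 15 of 17 (15 adjusted over the list alone, median 3.67, adjusted p = 1.66e-07, and adjusted p = 0.314 with an estimated correlation). Top2a rose by 5.77. Hypoxia and glycolysis genes rose in 8 of 15 (9 adjusted over the list alone, median 1.97, adjusted p = 0.00113, and adjusted p = 0.480 with an estimated correlation). Pgk1 rose by 4.06 and Ndrg1 by 3.65. Basement membrane and integrin genes did not pass as a list (5 up and 2 down of 12, 7 and 2 adjusted over the list alone, median 0.99, adjusted p = 0.388), nor did p53 targets (3 up and 4 down of 17, 4 and 4 adjusted over the list alone, median 0.02, mean -0.34, adjusted p = 0.873), in which Pmaip1 rose by 3.83 and the cell cycle inhibitor Cdkn1a fell by 3.55.

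Among immune-related lists, MHC class II genes fell in 7 of 7 (7 adjusted over the list alone, median -6.61, adjusted p = 8.38e-09, and adjusted p = 0.213 with an estimated correlation) and MHC class I genes in 5 of 9 (6 adjusted over the list alone, median -1.80, adjusted p = 0.000217, and adjusted p = 0.375 with an estimated correlation), with the antigen-presenting H2-Aa down by 7.06 and H2-K1 by 2.97. Interferon genes rose in 5 of 14 (5 adjusted over the list alone, median 1.95, adjusted p = 0.0476, and adjusted p = 0.598 with an estimated correlation). Ifit1 rose by 4.41. Dissociation stress genes, which respond to tissue handling, fell in 11 of 13 (11 adjusted over the list alone, median -2.11, adjusted p = 5.58e-07, and adjusted p = 0.213 with an estimated correlation). Zfp36 fell by 4.23 and Jun by 3.36. Lists made for other cell types were also tested in these cells. For these lists, free RNA from other cells was not told apart from a change in carcinoma-like cells. Tumor 1 held 1628 cells of an unnamed cluster with Arg1 among its leading genes. Tumor macrophage genes rose in 5 of 14 (5 adjusted over the list alone, median 1.25, adjusted p = 0.0337, and adjusted p = 0.375 with an estimated correlation), led by Arg1 (3.35), and Spp1 (4.22) stood at 229 TMM-scaled CPM in tumor 1 and 3258 in tumor 2. Tumor endothelium genes rose in 1 and fell in 6 of 11 (1 and 6 adjusted over the list alone, median -0.93, adjusted p = 0.0226, and adjusted p = 0.215 with an estimated correlation) and naive T cell genes fell in 3 of 7 (3 adjusted over the list alone, median -2.35, adjusted p = 0.0142, and adjusted p = 0.213 with an estimated correlation). Activated fibroblast genes (4 up and 3 down of 13, 5 and 5 adjusted over the list alone, median -0.92, mean 0.88, adjusted p = 0.901), T cell activation genes (1 and 1 of 10, 0 and 1 adjusted over the list alone, median -0.30, mean 0.29, adjusted p = 0.409) and tumor neutrophil genes (1 and 0 of 8, 0 and 0 adjusted over the list alone, median 0.38, mean -0.21, adjusted p = 0.901) did not pass.

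Without lung 1 the count of changed genes was 2666 and without lung 2 it was 2846, against 5202, and within batch 240705 it was 6457. Of the named genes that passed, 15 and 16 lost the call without lung 1 or lung 2, among them Spp1, Hnf4a, Pdx1 and Ifit1 in both, and Yap1 without lung 2. The call of Pdx1 also ended without tumor 1 and without either line replicate. Scaling by RLE or DESeq2 size factors moved the median of all genes from 0.22 to 0.09 and 0.07, so the sign of a list median nearer to 0 than that shift, as for MAPK output and p53 targets, is not settled.

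**Figure D3:**
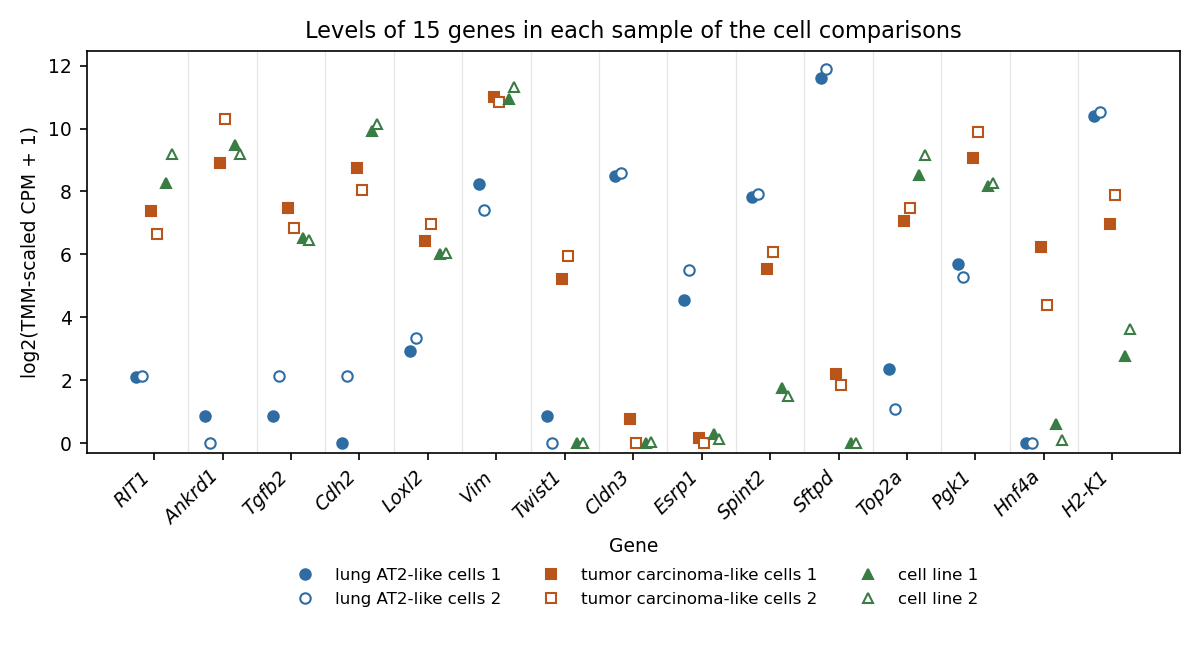
Level of 15 genes (x axis) as log2 of TMM-scaled CPM plus 1 (y axis) in each of the 6 samples of the cell comparisons; points are samples and shapes are groups, with filled points for sample 1. RIT1 averaged 3.36 CPM in AT2-like cells, 132 CPM in carcinoma-like cells and 446 CPM in the line, and Twist1 averaged 48.6 CPM in carcinoma-like cells and had 0 counts in the line.

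The line was compared with carcinoma-like cells to ask which features of tumor cells a cultured line shares. Which tumor the line was grown from is unknown here. Effects of culture and differences between tumors therefore cannot be told apart in this comparison. Camera called proliferation genes higher and interferon, MHC class I and gut lineage genes lower, and none of these with an estimated correlation (adjusted p = 0.346, 0.346, 0.346 and 0.244). The branched-chain aminotransferase Bcat1 (chromosome 6, 144993835 to 145076184) rose by 6.26 (SE 0.836, adjusted p = 0.00151), from 2.48 to 106 CPM, and the cystine transporter Slc7a11 by 4.07, while the immunoproteasome subunit Psmb8 (chromosome 17, 34197721 to 34201454) went from 51.5 CPM to 0 UMIs, at least 2374-fold lower. The EMT transcription factor Twist1 (chromosome 12, 33957671 to 33959829) was at least 2269.7-fold lower in the line, with 0 UMIs against 2050 UMIs. Of 16551 genes, 6137 changed with edgeR, 2546 higher and 3591 lower in the line, though within batch 240705 (2730 and 2663) and without tumor 1 (2431 and 2423) the larger part was higher. RIT1 was higher by 1.74 (SE 0.363, adjusted p = 0.00684), Yap1 by 0.95, Tead1 by 0.82 and Tead4 by 2.09 (adjusted p = 0.0381, 0.0208 and 0.00315).

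Further rises included Cth of cysteine synthesis (4.98), the phosphatase Ppef1 (4.97), the lectin Siglecg (4.93), the collagen Col5a2 (4.86), the glutathione transferase Gsta1 (4.80), the ankyrin Ank2 (4.76), the proteoglycan Bgn (4.26), Clca3a1 (3.91) and the FGF-binding protein Fgfbp1 (3.88). Among the falls, Apob fell by 12.37 and the protocadherin Pcdh7 had a log2 fold change of -11.22, and a single UMI remained in the line of Bex1 (ratio 2.67e-05, 95% interval 6.76e-07 to 0.000149), Cdh6 (2.96e-05, 7.48e-07 to 0.000165), the fatty acid receptor Ffar4 (6.1e-05, 1.54e-06 to 0.00034) and Igfbp2 (6.93e-05, 1.75e-06 to 0.000386). The same held for the transcription elongation factor Elof1 (0.000104, 2.64e-06 to 0.000581), complement C3 (0.000134, 3.39e-06 to 0.000748) and Cthrc1 (0.00016, 4.04e-06 to 0.00089), and 2 UMIs remained of the transcription factor Pax2 (0.000299, 3.62e-05 to 0.00108) and the prostaglandin-degrading enzyme Hpgd (0.000323, 3.9e-05 to 0.00117).

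YAP/TEAD targets split, with 4 up and 5 down of 22 (5 and 7 adjusted over the list alone, median -0.47, adjusted p = 0.256): Fjx1 fell by 8.63, Nt5e by 4.90 and the tissue factor gene F3 by 3.11. Mesenchymal genes fell in 12 of 27 and rose in 4 (13 and 4 adjusted over the list alone, median -0.68, adjusted p = 0.0413, and adjusted p = 0.346 with an estimated correlation). Prrx1 fell by 8.78. Epithelial junction genes fell in 11 of 21 (11 adjusted over the list alone, median -2.79, adjusted p = 0.000941, and adjusted p = 0.244 with an estimated correlation). Spint2 fell by 4.73. Proliferation genes rose in 16 of 17 (16 adjusted over the list alone, median 1.60, adjusted p = 1.45e-07, and adjusted p = 0.346 with an estimated correlation). Bub1 rose by 2.45. Gut lineage genes fell in 6 of 7 (6 adjusted over the list alone, median -6.22, adjusted p = 0.00339, and adjusted p = 0.244 with an estimated correlation). Hnf4a fell by 7.22. Alveolar lineage genes (1 up and 7 down of 15, 2 and 7 adjusted over the list alone, median -1.61) and T cell activation genes (1 and 5 of 10, 1 and 5 adjusted over the list alone, median -1.76) did not pass (adjusted p = 0.0991 for each). Injury-related genes fell in 6 and rose in 1 of 11 (8 and 1 adjusted over the list alone, median -0.91, adjusted p = 0.00357, and adjusted p = 0.244 with an estimated correlation), and hypoxia genes fell in 8 of 15 (10 adjusted over the list alone, median -1.30, adjusted p = 0.00268, and adjusted p = 0.386 with an estimated correlation). Egln3 fell by 5.77.

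Interferon genes fell in 12 of 14 members (12 adjusted over the list alone, median -4.98, adjusted p = 3.69e-05, and adjusted p = 0.346 with an estimated correlation). Irf7 fell by 6.47. MHC class I genes fell in 8 of 9 (8 adjusted over the list alone, median -5.48, adjusted p = 0.000116, and adjusted p = 0.346 with an estimated correlation): the peptide transporter Tap1 was at least 423-fold lower and Psmb9 at least 317-fold lower. Dissociation stress genes fell in 13 of 13 (13 adjusted over the list alone, median -3.53, adjusted p = 1.71e-06, and adjusted p = 0.246 with an estimated correlation). Fos fell by 9.27. The line was trypsinized from culture, not dissociated from tissue. Macrophage, fibroblast and MHC class II genes, of which tissue cells can carry free RNA from neighboring cells, fell too: 10 of 14, 11 of 13 (1 rose) and 6 of 7 members, or 11, 11 (1 rose) and 6 (1 rose) adjusted over the list alone (adjusted p = 0.000208, 0.00102 and 0.00579, and adjusted p = 0.246, 0.244 and 0.346 with an estimated correlation). Without line replicate 1 the count of changed genes was 2613, without line replicate 2 it was 2475, and within batch 240705 it was 5393. The calls of RIT1, Yap1 and Tead1 ended without line replicate 2, those of Yap1 and Tead1 also without line replicate 1 or either lung sample, and that of Yap1 without tumor 2. Thinned to equal cells and UMIs, 830 genes changed and 28.9% of them were higher, against 41.5%.

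Comparing the line with AT2-like cells completed the set. Camera called MHC class I and II genes lower in the line and proliferation genes higher, and none of these lists with an estimated correlation (adjusted p = 0.351, 0.266 and 0.294). The surfactant gene Sftpd (chromosome 14, 41172214 to 41185149) had 3428 CPM in AT2-like cells and 0 UMIs in the line, the lung lineage transcription factor Nkx2-1 was at least 8203-fold lower and H2-Ab1 at least 50093-fold lower. Ankrd1 stood at 651 ± 88.3 CPM, a ratio of 1144 (205 to 45169), and Cdh2 at 1039.9 ± 111 CPM, a ratio of 588 (201 to 2851). Of 16551 genes, 8341 changed with edgeR, 4342 higher and 3999 lower, and RIT1 rose by 7.05 (SE 0.550, adjusted p = 2.46e-05). The larger part was lower with DESeq2 (3584 higher and 4677 lower), with RLE size factors (3611 and 4456) and when thinned (1486 and 1971). It was also lower without line replicate 1 (2965 and 3256), line replicate 2 (2958 and 3155) or lung 2 (3089 and 3111) and with the lung samples summed (3395 and 3485). Genes with 0 counts in AT2-like cells that rose most were Hist1h1b (at least 263-fold), Hs6st2 (142-fold), Serpinb9b (122-fold), Gsta1 (106-fold), Pak3 (64.3-fold), Bcat1 (60.2-fold), Adh7 (53.5-fold), Flnc (50.5-fold), Palm3 (46.1-fold), Sall3 (43.5-fold), Cenph (43.0-fold) and Rad51ap1 (40.2-fold), each as a lower bound.

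YAP/TEAD targets rose in 12 of 22 and fell in 2 (12 and 2 adjusted over the list alone, median 1.15, or 1.06 with bounds, adjusted p = 0.0286, and adjusted p = 0.264 with an estimated correlation). Axl rose by 4.37 and Tgfb2 by 5.51. Epithelial junction genes fell in 18 of 21, alveolar lineage genes in 14 of 15, MHC class I genes in 9 of 9 and dissociation stress genes in 13 of 13 (adjusted p = 4.65e-08, 4.65e-08, 1.49e-05 and 4.65e-08, and adjusted p = 0.199, 0.264, 0.351 and 0.264 with an estimated correlation), with the same counts adjusted over the list alone. MHC class II genes fell in 7 of 7 (7 adjusted over the list alone, adjusted p = 7.74e-06, and adjusted p = 0.266 with an estimated correlation). Proliferation genes rose in 17 of 17 (17 adjusted over the list alone, median 4.95, adjusted p = 4.59e-08, and adjusted p = 0.294 with an estimated correlation). Mesenchymal genes split, with 8 up and 7 down of 27 (8 and 8 adjusted over the list alone, median -0.27, or -0.17 with bounds, adjusted p = 0.845), and MAPK output genes too, with 5 up and 7 down of 14 (5 and 7 adjusted over the list alone, median -0.03, mean 0.50, adjusted p = 0.845). Wwtr1 fell by 0.85 and Tead1 and Tead4 rose by 1.32 and 2.43, while Yap1 (-0.29) did not pass (adjusted p = 0.464). The call of Wwtr1 ended without either lung sample or either line replicate, and that of Sall3 without either lung sample. Scaling by RLE or DESeq2 size factors moved the median of all genes from 0.23 to 0.00 and -0.06. Within batch 240705 the count was 8469.

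**Figure D4:**
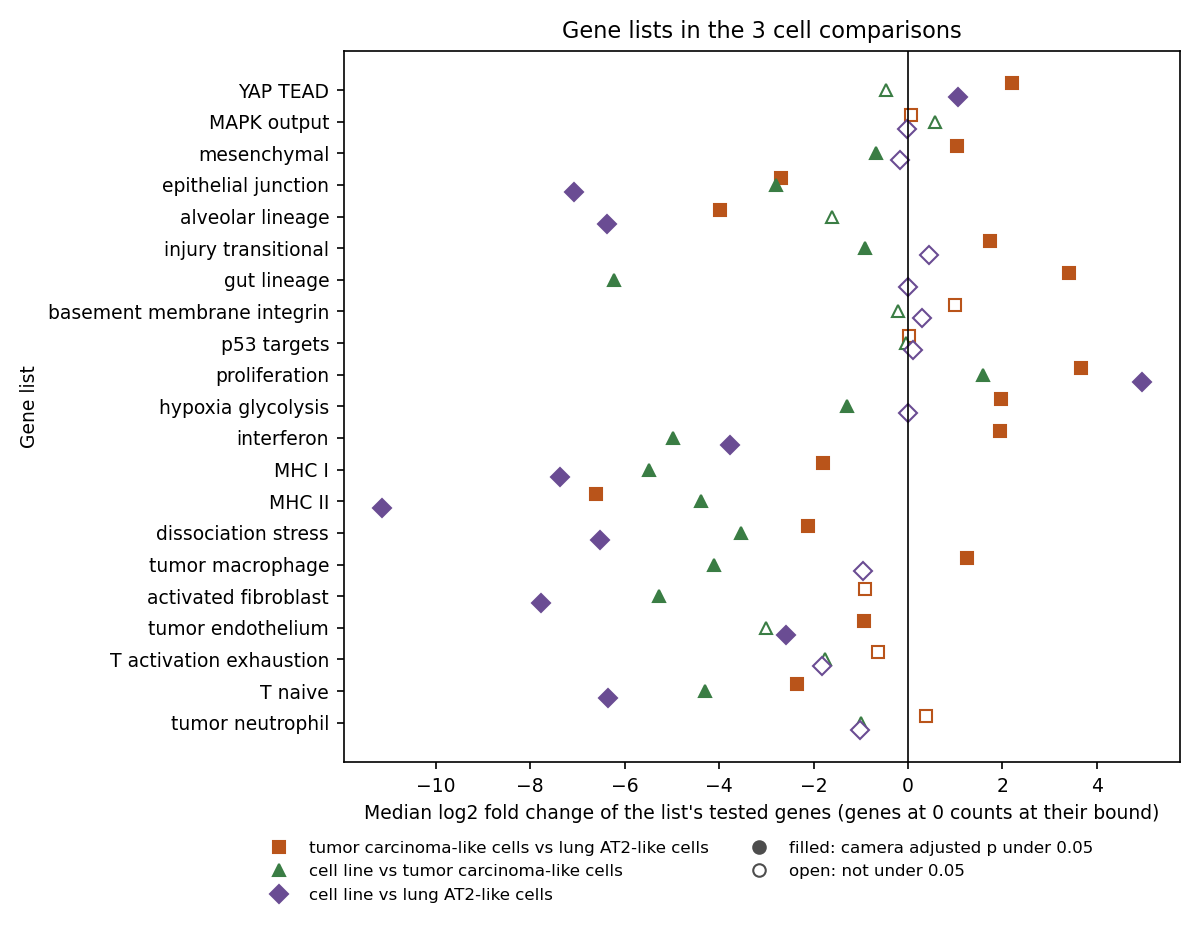
Median log2 fold change (x axis) of 21 gene lists (y axis) in the 3 cell comparisons, with genes at 0 counts at their bound; filled symbols passed camera at adjusted p under 0.05, and none passed with an estimated correlation. YAP/TEAD targets had medians of 2.20 in tumor carcinoma-like cells and 1.06 in the line against AT2-like cells, and -0.47 between the line and carcinoma-like cells.

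All cells of a sample were also summed, so that whole tumor could be set beside whole lung without naming cells. Camera called macrophage, hypoxia, mesenchymal and proliferation genes higher in the tumors, and none of these lists with an estimated correlation (adjusted p = 0.415 for each). Arg1 (chromosome 10, 24915221 to 24927484), an arginase of wound-type macrophages, rose by 2.97 (SE 0.223, adjusted p = 0.00679), from 112 and 106 CPM in the lungs to 875 and 834 CPM. The hypoxia-induced factor gene Epas1 (chromosome 17, 86753700 to 86833410), abundant in lung endothelium, fell by 5.50 (SE 0.208, adjusted p = 0.0044). Of 20105 genes tested with edgeR, 1881 changed, 831 higher and 1050 lower in the tumors.

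Further rises included the adhesion molecule Ncam1 (3.94), the matrix protein Fbln2 (3.68), Cdh2 (3.67), Pkhd1 (3.63), Apob (3.61), Gldc (3.58), Onecut2 (3.41), RIT1 (3.40, adjusted p = 0.0379), the neutrophil chemokine Cxcl3 (3.37), Ankrd1 (3.32), Sprr1a (3.29) and Hs6st2 (3.24). The largest falls were in Glp1r (-8.25), Rgs6 (-7.26), Tmem100 (-7.14), Scn7a (-6.89), Bmp6 (-6.26), Fendrr (-6.13), the lung mesenchyme factor Foxf1 (-6.12), Fmo1 (-5.94), Samd12 (-5.87), Tbx3 (-5.84) and Cyp4b1 (-5.66). Rit1, Trp53, Nf2, Yap1, Wwtr1, Tead1 and Tead4 did not pass the test (log2 fold changes -0.23, 0.02, 0.03, -0.20, -0.62, 1.39 and -1.46).

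Mesenchymal genes rose in 9 of 27 (15 up and 1 down adjusted over the list alone, median 1.35, adjusted p = 3.69e-06, and adjusted p = 0.415 with an estimated correlation). Twist1 rose by 3.45 and Loxl2 by 2.57. Proliferation genes rose in 10 of 17 (16 adjusted over the list alone, median 1.02, adjusted p = 6.44e-07, and adjusted p = 0.415 with an estimated correlation). Ccnb2 rose by 1.39. Hypoxia genes rose in 6 of 15 (9 adjusted over the list alone, median 1.55, adjusted p = 4.34e-06, and adjusted p = 0.415 with an estimated correlation). The hexokinase Hk2 rose by 2.55. Tumor macrophage genes rose in 4 of 14 (9 adjusted over the list alone, median 1.68, adjusted p = 6.63e-05, and adjusted p = 0.415 with an estimated correlation). Hmox1 rose by 2.22 and Trem2 by 1.29. Activated fibroblast genes rose in 3 of 13 (5 adjusted over the list alone, median 1.26, adjusted p = 0.000512, and adjusted p = 0.415 with an estimated correlation). The collagen Col11a1 rose by 6.97. YAP/TEAD targets rose in 6 of 22 and fell in 1 (9 and 2 adjusted over the list alone, median 0.87, adjusted p = 0.00551, and adjusted p = 0.415 with an estimated correlation). F3 rose by 2.39 and Lats2 fell by 0.77. Injury-related genes rose in 4 of 11 (6 adjusted over the list alone, median 1.04, adjusted p = 0.000239, and adjusted p = 0.415 with an estimated correlation). Clu rose by 2.39. Naive T cell genes fell in 3 of 7 (4 adjusted over the list alone, median -1.69, adjusted p = 0.000554, and adjusted p = 0.415 with an estimated correlation). S1pr1 fell by 2.67. Tumor endothelium genes did not pass as a list (0 up and 2 down of 11, adjusted p = 0.17). Plvap fell by 3.42 and Dll4 by 2.49. Shares of cell classes differed between tumor and lung as given above, and bulk sums carry those shares.

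These whole-tissue calls rest on a spread that each control library changes. Within batch 240705 the spread is only that between samples of 1 lung, so its count says nothing of the spread between tumors. Without lung 1 the count was 4 and without lung 2 it was 32, against 1881, without line replicate 1 or 2 it was 402 or 406, without tumor 1 it was 4395 and without tumor 2 it was 7898, and within batch 240705 it was 10320 genes. Of the 65 named genes that passed, 63 and 60 lost the call without lung 1 or lung 2 and 43 without either line replicate, among the last RIT1 and Cdh2. DESeq2 called 4242 genes, 2241 higher and 2001 lower, and without tumor 2 there were 4085 higher and 3813 lower.

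Within cell classes, tumor and lung were compared where all 4 samples held enough cells, to ask how non-malignant cells in the tumors differed from those of adjacent lung. T-like cells carried more of the exhaustion receptor Pdcd1 (chromosome 1, 94038305 to 94052553), which rose by 1.81 (SE 0.192, adjusted p = 0.0412) from 69.6 and 59.7 CPM to 253 and 200.5 CPM, and of the co-stimulatory receptor Tnfrsf9 (1.81). The inhibitory receptor gene Lilrb4a (1.71) and the ceramide kinase Cerk (1.63) rose, and the arrestin Arrdc3 (-2.28) and the nuclear exporter Xpo1 (-1.83) fell. These 6 genes were all that passed edgeR of 10485 tested. A cluster led by Icos, Tox and Tnfrsf4 held 409 and 276 T-like cells of the lungs and 136 and 52 of the tumors. One led by Lef1 held 431 and 294 against 69 and 33, and one led by Ccl5 346 and 228 against 64 and 29. A rise within cells and a shift in this makeup cannot be told apart. T cell activation genes rose in 2 of 15 (7 up and 2 down adjusted over the list alone, median 0.87, adjusted p = 1.04e-05, and adjusted p = 0.259 with an estimated correlation). In that list Ifng fell by 1.99 and Tnfrsf4 rose by 1.21, neither past edgeR over all genes (adjusted p = 0.0571 and 0.0597). Naive T cell genes (median -0.40, 2 down adjusted over the list alone, adjusted p = 0.000575), interferon genes (0.70, 4 up adjusted over the list alone, adjusted p = 0.0162), hypoxia genes (0.32, 3 up adjusted over the list alone, adjusted p = 0.00684), MHC class II genes (-2.29, 5 down adjusted over the list alone, adjusted p = 5.02e-06), MHC class I genes (-0.18, adjusted p = 0.0361) and dissociation stress genes (-0.53, 5 down adjusted over the list alone, adjusted p = 3.42e-05) also passed camera, with adjusted p = 0.259, 0.514, 0.416, 0.318, 0.416 and 0.318 with an estimated correlation, and proliferation genes did not (0.09, adjusted p = 0.847). The MHC class II gene H2-Ab1 stood at 45.8 and 70.6 CPM in T-like cells of the lungs, against 3652 and 3922 CPM in macrophage-like cells there. Free RNA from other cells was not told apart from a change in T-like cells. The count of 6 rose to 72 without lung 1, 63 without lung 2, 1019 without tumor 1, which is also batch 240705 alone, and 2010 without tumor 2. It was 0 with doublets kept or no low-count filter and 84 with DESeq2. The call of Tnfrsf9 ended without lung 1.

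Macrophage-like cells of the tumors expressed more Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, which rose by 2.04 (SE 0.235, adjusted p = 0.044), and more of the lipid phosphatase Plpp3 (2.22). Cell cycle genes were lower: Birc5 fell by 2.06, Cdk1 by 1.81 and Top2a by 1.77, and Epas1 and Stxbp6 fell by 2.69 and 2.50. Of 11596 genes, 44 passed edgeR, 5 higher and 39 lower in the tumors. Proliferation genes fell in 3 of 17 (15 adjusted over the list alone, median -1.51, adjusted p = 2.33e-15, and adjusted p = 0.232 with an estimated correlation), tumor macrophage genes rose in 1 of 14 (2 adjusted over the list alone, median 0.56, adjusted p = 0.000524, and adjusted p = 0.440 with an estimated correlation), hypoxia genes had a median of 0.40 (adjusted p = 0.00142) and MHC class II genes of -1.14 (adjusted p = 0.0133), each with adjusted p = 0.440 with an estimated correlation and no member past the test. Most of the MHC class II difference lay in tumor 1, alone in its batch: H2-Ab1 stood at 285 CPM in it and 2992 CPM in tumor 2, against 3652 and 3922 CPM in the lungs. Interferon, MHC class I and dissociation stress genes did not pass (adjusted p = 0.233, 0.107 and 0.107), the first and last with a median of 0.01 and -0.08 and a mean of -0.13 and 0.10. Without lung 1 the count was 10 and without lung 2 it was 0, and all 7 named calls ended. It was 2040 without tumor 1 (batch 240705 alone), 4807 without tumor 2 and 319 with DESeq2.

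Dendritic-like cells of the tumors had more Ccdc80 (5.39), the growth factor Nrg1 (3.19), Trem2 (2.96), Arhgap24 (2.81), the stress-induced Ddit4 (2.70) and the apolipoprotein Apoe (2.56). They had less Cd207 (chromosome 6, 83671215 to 83677857), the langerin of a dendritic cell subset, with 2 UMIs against 629 UMIs (ratio 0.00734, 95% interval 0.000887 to 0.0266), and less Frmd5 (-5.67), Pcdh7 (-4.78), Airn (-3.74), Cacnb2 (-3.67) and the nuclease Dnase1l3 (-3.54). Of 10131 genes, 184 passed edgeR, 45 higher and 139 lower. Hypoxia genes rose in 3 of 13 (9 adjusted over the list alone, median 1.16, adjusted p = 2.45e-08, and adjusted p = 0.116 with an estimated correlation). Vegfa rose by 1.59. Dissociation stress genes fell in 1 of 13 members, Atf3 (-1.89, 7 members adjusted over the list alone, median -0.90, adjusted p = 7.61e-07, and adjusted p = 0.116 with an estimated correlation). Interferon genes (0.88, 2 up adjusted over the list alone), proliferation genes (0.61) and MHC class I genes (-0.37) passed camera (adjusted p = 0.000749, 0.00084 and 0.0241, and adjusted p = 0.437, 0.437 and 0.491 with an estimated correlation), and MHC class II genes did not (adjusted p = 0.0637). Without lung 1 or lung 2 the count was 1 or 0, and 16 and 17 of 17 named calls ended. It was 1342 without tumor 1 (batch 240705 alone), 2821 without tumor 2 and 338 with DESeq2.

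In B-like, neutrophil-like and plasmacytoid dendritic-like cells edgeR called 0 genes, of 9414, 7942 and 5261 tested. At an unadjusted p under 0.05 there were 1276, 1417 and 447 genes, and DESeq2 called 28, 310 and 0 genes. Neutrophil-like cells came mostly from different clusters in tumor 1, in tumor 2 and in the lungs (1187 of the 1553 cells of 1 cluster from tumor 1, 399 of the 502 of another from tumor 2, and 450 and 435 of the 974 of a further cluster from lungs 1 and 2). In them, hypoxia genes (median 1.33, 5 up adjusted over the list alone, adjusted p = 3.98e-05), MHC class II genes (-2.48, 5 down adjusted over the list alone, adjusted p = 0.00219), MHC class I genes (-0.55, adjusted p = 0.00488), interferon genes (0.91, adjusted p = 0.0326) and tumor neutrophil genes (0.90, 1 up adjusted over the list alone, adjusted p = 0.0326) passed camera, with adjusted p = 0.578, 0.578, 0.578, 0.611 and 0.621 with an estimated correlation, and dissociation stress genes did not (0.24, adjusted p = 0.641). The MHC class II gene H2-Aa stood at 253 and 57.1 CPM in the lung samples and 9.79 and 24.5 CPM in the tumors. A neutrophil-like cluster led by Adgre4 and Treml4 held 34 and 20 cells of the lungs and 0 of the tumors. Free RNA from other cells was not told apart from a change in neutrophil-like cells. The lipid droplet gene Hilpda stood at 211 and 238 CPM in the lungs and 702 and 1945 CPM in the tumors (log2 fold change 2.56, adjusted p = 0.0982). In plasmacytoid cells hypoxia (0.78, 2 up adjusted over the list alone), interferon (0.61), MHC class II (-0.63) and dissociation stress genes (-0.74, 2 down adjusted over the list alone) passed (adjusted p = 2.33e-05, 0.0235, 9.98e-05 and 0.000582, and adjusted p = 0.204, 0.388, 0.367 and 0.204 with an estimated correlation), and MHC class I genes did not (0.19, adjusted p = 0.105). There too H2-Ab1 was lowest in tumor 1, at 305 CPM against 1186 CPM in tumor 2 and 1509 and 1873 CPM in the lungs. In B-like cells dissociation stress genes (-0.55, 3 down adjusted over the list alone, adjusted p = 0.0218) and MHC class I genes (-0.17, 1 down adjusted over the list alone, adjusted p = 0.0407) passed, with adjusted p = 0.557 and 0.752 with an estimated correlation, and hypoxia, proliferation, MHC class II and interferon genes did not (adjusted p = 0.11, 0.661, 0.661 and 0.849). Leaving out lung 1, lung 2, tumor 1 or tumor 2 gave other counts: from 32 to 1175 in B-like cells, from 25 to 340 in plasmacytoid cells and up to 2546 in neutrophil-like cells, where both lungs gave 0. Batch 240705 alone gave 964, 260 and 2477 genes in B-like, plasmacytoid and neutrophil-like cells.

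The carcinoma-like cells of the tumors were set beside each other by library, to ask whether both tumors held the same state. They came from a shallow cluster (median depth 0.404 of the library median) and a deep one (4.63 times the library median). Tumor 2 had 115 cells in the shallow and 38 in the deep cluster, and tumor 1 had 422 and 1263. RIT1, Ankrd1, Cdh2 and Vim were abundant in both, Ankrd1 at 493 and 619.8 CPM (of plain library totals, here and below) in the libraries of tumor 1 and 1197 CPM in tumor 2, and Cdh2 at 477, 518 and 250.2 CPM. The secreted protein gene Spp1 stood at 281, 241 and 3110.3 CPM, the interferon gene Ifit1 at 13.5, 17.9 and 66.2 CPM, and Hnf4a at 83.2, 88.1 and 19.0 CPM. As the median log2 ratio of tumor 1 over tumor 2, gut lineage genes stood at 2.11, with only 3 of 5 members above 0. Dissociation stress genes stood at 1.16, basement membrane genes at 0.92 and mesenchymal genes at 0.65. Medians were -1.07 for interferon genes, -0.94 for hypoxia genes, -0.84 for MHC class II, -0.67 for MHC class I and 0.18 for YAP/TEAD targets. The median of YAP/TEAD targets lay at the percentile 11.8 of random lists of the same size, and those of mesenchymal and gut lineage genes at 99.1 and 100. With 1 tumor on each side, sequenced in different batches, no test was run. Tumor, batch and the split between the shallow and the deep cluster cannot be told apart.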

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

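All tests of explanations below were chosen after the result was seen, and differences between classes were not tested.

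RIT1 appeared in cells of adjacent lung, outside the comparisons of the report: carcinoma-like cells held 126 and 101 CPM in lung 1 and lung 2, near the 95.03 CPM of tumor 2. Their source was not tested. Alveolar macrophage-like cells of lung 1 held a RIT1 UMI in 2.18% of cells thinned to 2000 UMIs, against 0.454% of its lymphocytes, and in lung 2 the shares were 1.95% and 0.557%.

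For these macrophages, an equal amount of free RNA in each droplet is excluded, since the lower bound of their RIT1 UMIs per cell was 2.62 times the highest upper bound of 6 other classes in the lung sample where it was lower. This test replaced one on the thinned shares, which had met its bound in 1 of 2 lung samples and left the source open. Reads of the mouse gene Rit1 are excluded by the ratio of RIT1 to Rit1 UMIs, with a lower bound of 0.288 against upper bounds of 0.0614 in macrophages of tumor 1 and 0.185 in lung lymphocytes. RNA taken up from carcinoma-like cells could raise RIT1, but 20 of their other genes stood at a median of 0.0110 of the level that this needs (upper quartile 0.0341), with the exception of Krt19 at 2.40. No biological explanation was tested.

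Dissociation stress genes, as mean log2 CPM of tumor minus lung, stood at -0.61 in B-like, -0.62 in T-like, -0.90 in dendritic-like and -0.75 in plasmacytoid cells and at 0.66 in neutrophil-like cells. The tumors differed in these means. Neutrophil-like cells stood at 8.24 in tumor 1 and 9.37 in tumor 2, against 8.19 and 8.11 in the lungs. Dendritic-like cells stood at 6.64 and 7.91, against 8.21 and 8.14. Sequencing batch could account for the lower values in tumor. Tumor 2, of the same batch as the lungs, lay below both in 4 of 6 classes, fewer than the 5 that would exclude batch. A test added after that outcome, in the 4 classes where both tumors lay lower, found tumor 2 lower by more than the gap between the lungs in 3. It decides nothing, since those classes were picked by where tumor 2 lay and the gap is one between samples of 1 lung, so batch stays open. Handling of the tissue pieces would move the list the same way in each class, and 0 of 6 classes had both tumors above both lungs by more than the gap between these, so handling cannot be told apart from a change in the cells. A first bound had counted neutrophil-like cells, where the lower tumor lay above the higher lung by 0.0537, less than the gap of 0.0769, and no biological explanation was tested.

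Classes also moved apart in other lists, as mean log2 CPM of tumor minus lung. Interferon genes stood at 0.92 in dendritic-like and 0.82 in neutrophil-like cells and at -0.40 in B-like cells. Hypoxia genes stood at 1.18 in neutrophil-like, 1.12 in dendritic-like, 0.85 in plasmacytoid, 0.43 in T-like and 0.42 in macrophage-like cells and at -0.48 in B-like cells. MHC class I genes stood at 0.22 in plasmacytoid cells and at -0.68 in neutrophil-like, -0.37 in B-like, -0.28 in macrophage-like and -0.23 in T-like cells. Proliferation genes stood at 0.71 in dendritic-like and -1.44 in macrophage-like cells.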

How the results depend on the processing

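Across the alternatives 90 of 169 gene counts stayed within 1.5 times the reported one and 79 moved. Of 11652 values of named genes, 10415 kept direction and call, 597 gained and 560 lost the call, 75 moved and 5 reversed. Of 140 shares of a class in 1 sample 98 stayed within their interval and 42 moved. The counts of carcinoma-like, AT2-like and line comparisons stayed within 1.5 times under DESeq2, RLE size factors and other cell filters, and those of whole tissue and classes moved under DESeq2, in the batch alone or when samples were left out, except plasmacytoid cells under DESeq2 and neutrophil-like cells without either lung sample, which stayed at 0. The cause was not tested except where named.

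Genes past the test, for whole tissue and then B-like, dendritic-like, macrophage-like, neutrophil-like, plasmacytoid and T-like cells where they moved, were as follows. DESeq2 gave 4242, and in B-like 28, dendritic-like 338, macrophage-like 319, neutrophil-like 310 and T-like cells 84. No low-count filter gave 1190 in dendritic-like, 1036 in macrophage-like, 136 in neutrophil-like, 129 in plasmacytoid and 0 in T-like cells. With the 3 tumor libraries separate, which takes libraries of 1 tumor as replicates, counts were 4397, 35, 564, 354, 329 and 51, with no value in plasmacytoid cells, since the libraries of tumor 1 held under 20 each. With the 2 lung samples summed, which leaves 1 lung sample, they were 3354 in carcinoma-like against AT2-like cells, 32 in whole tissue (0 higher), 47 in B-like, 0 in dendritic-like, 33 in plasmacytoid and 79 in T-like cells. Batch 240705 alone gave 10320, 964, 1342, 2040, 2477, 260 and 1019.

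Leaving out 1 sample, with the lone sample of a group assumed to vary like the other groups, gave from 2666 to 6132 in carcinoma-like against AT2-like cells, 2475 to 7632 in the line against carcinoma-like cells, 5756 to 9422 in the line against AT2-like cells, 4 to 7898 in whole tissue, 32 to 1175 in B-like, 0 to 2821 in dendritic-like, 0 to 4807 in macrophage-like, 0 to 2546 in neutrophil-like, 25 to 340 in plasmacytoid and 63 to 2010 in T-like cells. Counts were highest without a tumor, which leaves the spread to samples of 1 lung or 1 line. Thinning to equal cells and UMIs gave 2271, 830 and 3457 in the 3 cell comparisons, where 7182 genes were tested. Cells, UMIs and tested genes fell together there, so depth alone was not tested. Of the genes called, 43.6% were higher in carcinoma-like than in AT2-like cells, against 54.2%, and without a line replicate 22.6% and 23.2% were higher in whole tumor, against 44.2%.

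With the sample number as a replicate block, counts were 1140 in whole tissue, 56 in B-like, 679 in dendritic-like, 288 in macrophage-like, 146 in neutrophil-like and 15 in T-like cells. In the cell and whole-tissue fits the numbers do not pair samples: correlations of residuals between equal numbers were from -0.0164 to 0.0664. This was not computed in the class fits.

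Kept doublets gave 0 in T-like cells. Clustered anew, added after seeing the data, the stricter filter gave 3 in B-like, 156 in neutrophil-like and 0 in T-like cells and no value where AT2-like cells are needed, and kept doublets gave 104 in B-like, 19 in macrophage-like, 298 in neutrophil-like and 241 in T-like cells. Camera with an estimated correlation called 0 lists in each of the 10 comparisons. Fry called 13 lists in carcinoma-like against AT2-like cells, where camera at its preset correlation called 15. It called 19 in the line against carcinoma-like cells (camera 13), 14 in the line against AT2-like cells (11) and 9 in whole tissue (11). Within classes fry called 0 in B-like, dendritic-like, neutrophil-like and plasmacytoid, 1 in macrophage-like and 2 in T-like cells. Endothelial-like cells, as tumor minus lung, stood at -26.4 points at Leiden resolution 2, -29.6 with the stricter filter, -27.8 with doublets kept, and -29.4 and -27.2 clustered anew. Macrophage-like cells stood at 13.3, 11.9 and 13.1 points at resolution 2, with the stricter filter and with it clustered anew. Monocyte-like cells stood at -14.98 and -15.3 points with the stricter filter, the second clustered anew, and -12.3 with doublets clustered anew. Reversed were Ikzf2 in carcinoma-like cells when thinned (-0.35), Cldn3 in the line against carcinoma-like cells in batch 240705 only (2.42) and without tumor replicate 1 (2.58, against -5.24 at the lowest without line replicate 2), where tumor 2 has 0 counts, Trem2 in the line against AT2-like cells without lung replicate 2 (1.67, against -8.33 without lung replicate 1), and Nf2 in whole tumor in batch 240705 only (-0.35).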

Other observations

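A cluster of RIT1-positive mesenchymal cells stood beside the carcinoma-like cells in tumor 1. It made up 6.79% of tumor 1 and 0.563% of tumor 2 and carried 268 CPM of RIT1, with a RIT1 UMI in 65.8% of cells (median 15819 UMIs) and in 36.9% after thinning. As the median log2 ratio of this cluster over carcinoma-like cells of tumor 1, mesenchymal genes stood at 2.05 (22 of 26 members above 0), epithelial junction genes at -3.35, gut lineage genes at -3.36, injury-related genes at -1.24, proliferation genes at -0.84 (0 of 17), dissociation stress genes at 0.90 (12 of 13, percentile 99.95 of random lists) and YAP/TEAD targets at 0.19 (percentile 82.3 of random lists). Loxl2 stood at 357 CPM against 98.6 and 94.96 CPM in carcinoma-like cells of the libraries, Inhba at 260.4 CPM against 52.9 and 67.6 CPM, and Clu at 261 CPM against 1537 and 1789 CPM. Activated fibroblast genes were higher in it (2.66), and it has no counterpart of enough cells in lung, so no test was run.

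Fibroblast-like cells of tumor 1 differed from those of the lungs in the same values. Activated fibroblast genes stood at a median log2 ratio of 3.35 (14 of 14 members above 0), mesenchymal genes at 1.69, proliferation genes at 0.96, MHC class II genes at -3.00, MHC class I genes at -1.05 (0 of 9) and dissociation stress genes at -1.002 (2 of 13, percentile 0.255 of random lists). Tumor 2 held 0 fibroblast-like cells, so this rests on 1 tumor in a batch of its own. The fibroblast-like cells came mostly from different clusters in tumor 1 and in the lungs. A cluster led by Mfap5, Dpt and Lum held 171 cells of tumor 1 and 45 and 36 of the lungs. One led by Inmt and C7 held 3 against 181 and 119. A change within cells and a shift in this makeup cannot be told apart.

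The tests in this part were all chosen after the result was seen. Carcinoma-like cells carried Msln, a mesothelial gene, at 961 and 352 CPM in the tumors against 219 CPM in mesothelial-like cells. A mesothelial marker profile could account for this, but only 2 of 7 markers reached 0.1 of the mesothelial level in both tumors: Msln, and Bnc1 at 21.3 and 13.7 CPM against 34.4 CPM. Wt1 stood at 22.7 and 34.1 CPM against 729 CPM and Upk3b at 1.96 and 0 CPM against 162 CPM, so the profile was not met in the tumors. In the carcinoma-like cells of the lungs (32 and 23 cells) Wt1 stood nearer to the mesothelial level at 116 CPM and Upk3b at 14.2 CPM, beside Msln at 360 CPM and Bnc1 at 5.41 CPM.

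Mesenchymal cells were unequal in the libraries of tumor 1, with 493 of 5437 cells (9.07%) and 235 of 5291 cells (4.44%). Barcodes with few UMIs may explain this, since above 10000 UMIs the shares were 13.1% and 12.96%, a ratio of 1.01.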
